A study of Mus musculus with 15 samples.

How the data were processed

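Gene expression was measured in mouse oocytes with Affymetrix arrays. Per the labels' protocols, females of the B6D2F1 hybrid strain received pregnant mare serum gonadotropin (PMSG), a hormone that stimulates follicle growth, and immature oocytes with a germinal vesicle (GV, the intact nucleus of the meiotically arrested oocyte) were collected 48 h later. GV oocytes were also matured in vitro for 16 h to metaphase II (MII, the stage at which the egg is ovulated), and in vivo matured MII oocytes were collected after stimulation with human chorionic gonadotropin. Cumulus cells, the somatic cells around the oocyte, were removed with hyaluronidase. Poly(A) RNA of pools of 150 oocytes was isolated on oligo(dT) beads and amplified over a pair of cycles before labelling, per the labels' protocols.

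The deposited values are intensities for 45101 probe sets on 15 arrays, made with MAS5 per the submitters' processing notes; its version and scaling target are not given in the sources used here. The deposited intensities are positive, on a linear scale and without missing values, from 0.0425 to 21563. The design written before the data were examined assumed arrays scaled to a common level. Array medians instead ran from 5.08 to 25.3, a range of 2.31 on the log2 scale, above the limit of 0.5 fixed in advance. By that rule quantile normalization of the log2 values across the 15 arrays became the setting reported here, and the intensities as deposited became an alternative.

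The 64 control probe sets were left out before normalization. The test covered the 22519 probe sets whose mean over all arrays lay in the upper 50% of the other 45037, which corresponds to a normalized log2 value of at least 3.07. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient for each of the 6 groups, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment within each comparison. Calls are probe sets with an adjusted p below 0.05. Counts of unadjusted p below 0.05 expected by chance assume no array effects shared between probe sets. Since array brightness was uneven between groups, an excess over such a count does not by itself show a group difference. The fit had 9 residual degrees of freedom. The labels do not say whether pools came from separate animals, so the p-values measure the spread between these samples, which may be technical. Replicate numbers follow the order of the records and pair no samples.

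Gene names came from the platform annotation, in which 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of the single symbols, 34754 were updated through their gene identifiers against the GRCm38.p6 gene table, used for names only. No coordinates are given. The tested probe sets named 12028 genes, each represented by its probe set with the highest mean. Ccnb1 and Gapdh are not named here, because no probe set outside the controls carried their symbol alone, and H1foo is listed under its current symbol H1f8.

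The rule for named genes was fixed before the data were examined. For each comparison of 2 groups it takes up to 10 genes with the largest rise and 10 with the largest fall among those with an adjusted p below 0.05, a log2 fold change of at least 1 and no overlap between arrays, or the 5 smallest p-values where fewer than 3 genes qualified. For the mean maturation difference and its dependence on age it takes the 5 smallest p-values in each direction. It adds up to 4 members of each gene list described, and a set of stage and reference genes in every group. The 19 gene lists and 4 lists of markers of other cell types were fixed at the same time and tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Marker genes were tested without the filter on low signal.

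Alternatives fixed in advance were the values as deposited, no filter, the upper 30% of probe sets, log2 of the intensity plus a pseudocount of 3.04, a fit to the compared arrays alone, variances without a trend, array weights, the number in the sample titles as a block of 2 levels (up to 12, and above), a number whose meaning is not known, and leaving out each array. Median scaling and a fit without 4 dim arrays were added after seeing the data. The methods were tested on simulated arrays with 200 changed probe sets among 22519. For the mean maturation difference, 91.0% of probe sets changed by 4 on the log2 scale, 55.2% of those changed by 2 and 7.58% of those changed by 1 were recovered, with 14 false calls. For adult in vivo MII against GV the shares were 59.7%, 19.4% and 1.52%, with 0 false calls, and for d20 against d26 they were 68.7%, 13.4% and 4.55%, with 2 false calls. Among 12028 simulated genes, camera recovered a proteasome list shifted by -1 with an adjusted p of 1.69e-28 and called 0 other lists. The simulated noise was independent between probe sets, so these simulations do not test false calls that arise when genes vary together. The number of arrays limits the precision of every value.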

Results

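The series holds 15 arrays of pooled mouse oocytes in 6 groups. Adult females, 7 to 8 weeks old, gave GV oocytes (n = 2), in vivo matured MII oocytes (n = 3) and in vitro matured MII oocytes (n = 2). Peripubertal females at day 26 (d26) gave in vivo (n = 2) and in vitro (n = 3) matured MII oocytes, and prepubertal females at day 20 (d20) gave in vitro matured MII oocytes (n = 3). No array duplicated another, since at most 0.00222% of values were identical in any of the 105 pairs.

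Arrays differed in brightness within groups. In 4 arrays only 2615 to 3042 probe sets exceeded a deposited intensity of 200, against 4882 to 9819 in the others. These dim arrays were adult in vivo replicate 1, adult in vitro replicate 2 and d26 in vitro replicates 2 and 3. Both GV arrays were the brightest, with 9819 and 9696 such probe sets. The hybridization controls, added just before hybridization, varied less, with geometric means from 1855 to 2838 in 14 arrays and 1211 in d26 in vitro replicate 3. The signal of the 3' Gapdh control probe set exceeded that of the 5' one 82.3 and 68.0 times in the 2 d26 in vivo arrays, where the 5' signal was only 0.76 and 3.99, and 12.6 to 26.6 times in the other 9 brighter arrays.

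**Figure D1:**
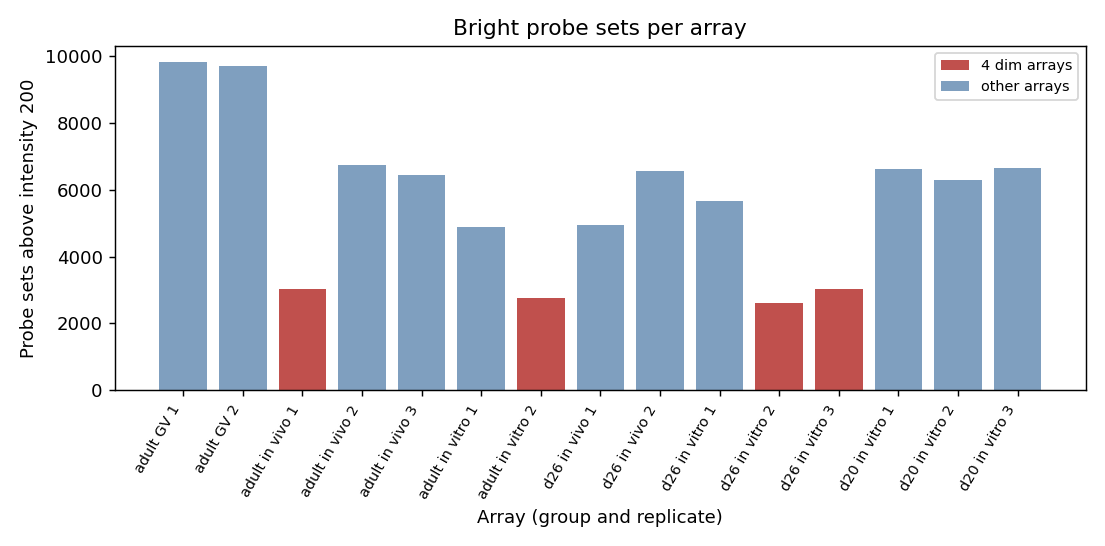
Bars give the number of probe sets with a deposited intensity above 200 (y axis) on each array (x axis, group and replicate). The 4 dim arrays, in red, have 2615 to 3042 such probe sets, and the others have 4882 or more.

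The first comparison asked how the transcripts of adult oocytes differ between the GV stage and MII after maturation in vivo. Transcripts for protein synthesis, respiration and protein turnover were lower at MII. Zp3, which encodes a zona pellucida glycoprotein, was 13.15 ± 0.15 on the log2 scale in GV oocytes (SD, n = 2) and 8.91 ± 0.38 in vivo at MII (SD, n = 3). Fdft1, squalene synthase, fell by 7.10 (SE 0.33, adjusted p = 4.61e-08), although another of its probe sets passed in the other direction (1.58, adjusted p = 0.0474), and Polr3a, the largest subunit of RNA polymerase III, fell by 7.77 (SE 0.45, adjusted p = 4.14e-07). The growth factors Gdf9 and Bmp15, secreted by oocytes, had log2 differences of -0.23 (SE 0.35) and -0.05 (SE 0.43) that did not pass, though another Bmp15 probe set was lower at MII (-2.37, adjusted p = 0.0096).

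In all, 3542 probe sets were higher and 2495 lower at MII after maturation in vivo, of 22519 tested by limma. These covered 2199 higher and 1478 lower genes, and 3359 genes met the size and separation rule. The largest falls also took in Tacc3 (-8.54), a spindle and centrosome protein, Copb2 (-7.94), a coatomer subunit, Aven (-7.70), Ppil3 (-7.39), Timm17a (-7.25), a subunit of the mitochondrial import machinery, Psmd14 (-7.24), a proteasome lid subunit, the general transcription factor Gtf2f1 (-7.14) and the recombination protein Psmc3ip (-6.71). The largest rises were Ctsc (4.69, SE 1.06) and Ctss (4.27, SE 0.84), both lysosomal cathepsins, Slfn4 (4.01, SE 1.37), the acute phase protein Saa3 (3.98, SE 0.99), Snhg8 (3.72), Pdgfra (3.69), Kynu (3.69), the oviductal glycoprotein Ovgp1 (3.63), Fgf16 (3.62) and Hivep2 (3.52). In GV oocytes 8 of these risers averaged under the filter level of 3.07, the exceptions being Saa3 at 3.38 and Ovgp1 at 3.73, and Gtf2f1 averaged under it at MII, so the sizes of these changes are imprecise. Saa3 was 7.36 ± 0.55 in adult in vivo MII oocytes (SD, n = 3), 4.89 ± 0.39 in d26 in vivo oocytes (SD, n = 2) and 2.37 ± 1.88 in adult in vitro oocytes (SD, n = 2). The Slfn4 call ended without a filter (adjusted p = 0.054), and with the values as deposited those of Slfn4, Saa3 and Ovgp1 ended (adjusted p = 0.188, 0.164 and 0.114). Slfn4 also did not pass without either GV array, adult in vivo replicate 1 or 3 or d20 in vitro replicate 1 (adjusted p from 0.0552 to 0.282) or with variances without a trend (0.0544), nor did Kynu without GV replicate 1 (0.0576), Snhg8 and Saa3 without GV replicate 2 (0.0874 and 0.085), or Fgf16 in a fit to the compared arrays alone (0.0978).

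Direction depended on the scaling. With the values as deposited, 23 probe sets were higher and 3481 lower, and the median probe set shifted by -0.98, against 0.24 after quantile normalization and 0.69 after median scaling. Without GV replicate 1 or 2 the total of 6037 calls became 3813 or 3308, and without the dim arrays 5259 probe sets were higher and 3483 lower.

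Adult oocytes matured in vitro were set against the same GV oocytes. The largest falls were Rpl7, a ribosomal protein (-8.89, SE 1.16, adjusted p = 9.83e-05), Psmd14 (-8.10), Ninj2 (-7.98), Cpsf4l (-7.95), the RNA ligase Rtcb (-7.95), Rdh11 (-7.85), Timm17a (-7.84), Tacc3 (-7.82), the proteasome ATPase Psmc1 (-7.65) and Aven (-7.54). The largest rises were Kynu (4.92, SE 0.93, adjusted p = 0.0012), Snhg8 (4.78), Hivep2 (4.52), the heat shock factor Hsf4 (4.46), Rap2c (4.33), Tpsb2 (4.21), the chromatin remodeller Chd1 (4.18), Sec24a (4.17), Zbtb1 (4.12) and the clock gene Per2 (4.03). Rap2c rose from 5.70 ± 0.02 (SD, n = 2) to 10.03 ± 0.58 (SD, n = 2). Zp3 fell by 4.14 (SE 0.39, adjusted p = 8.91e-06). Kynu, Snhg8, Hivep2, Hsf4, Tpsb2 and Per2 averaged under the filter level of 3.07 in GV oocytes, and Rpl7, Psmd14, Ninj2, Rtcb, Timm17a and Psmc1 did so at MII, so the sizes of these changes are imprecise.

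After maturation in vitro, 3607 probe sets were higher and 2641 lower than in GV oocytes, covering 2219 higher and 1549 lower genes. With the values as deposited 11 were higher and 6224 lower, with a median shift of -1.94 against 0.13 after quantile normalization and 0.59 after median scaling; Hsf4, Rap2c, Tpsb2, Chd1, Sec24a, Zbtb1 and Per2 then no longer passed (adjusted p from 0.0642 for Tpsb2 to 0.18 for Chd1). Hsf4 and Chd1 did not pass without GV replicate 1 (0.101 and 0.0899), Per2 without GV replicate 2 (0.0811), Aven without adult in vitro replicate 1 (0.0911), and Hsf4, Chd1, Per2 and Rdh11 without adult in vitro replicate 2 (0.0984, 0.113, 0.0672 and 0.0877). Without GV replicate 2 the total of 6248 became 3795.

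Both kinds of MII oocyte were compared with the same pair of GV arrays. The log2 fold changes of the 2 comparisons had a Pearson correlation of 0.85 across probe sets, against 0.208 in 100 simulations with no effect, and their covariance was 2.59 against 0.119, a difference of 2.47. The simulated noise followed array weights, which the reported fit does not use. The weight was 2.49 for both GV arrays, which gives them low noise, so the simulated values depend on that choice. Calls in common numbered 2940 higher and 1952 lower, where independent lists would share 567.3 and 292.6, and 0 probe sets were called in opposite directions. The GV arrays were not divided between the 2 comparisons, so part of the excess may come from the shared arrays.

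Lists fixed in advance placed the falls in housekeeping machinery. Counts cover only the members tested, and members without a tested probe set of a single symbol were left out. The ribosomal list was thus tested only in part. Of 44 cytosolic ribosomal protein genes, 28 fell and 2 rose after maturation in vivo (33 and 2 adjusted over the list alone), and 29 fell and 2 rose after maturation in vitro (31 and 2). Rps4x fell (-5.39 in vivo and -6.93 in vitro), as did Rpl7a (-5.22 and -4.89). Of 70 nuclear-encoded respiratory chain and ATP synthase genes, 44 fell and 1 rose in vivo (46 and 1 adjusted over the list alone), and 39 fell and 2 rose in vitro (41 and 2). Ndufv1 of complex I fell (-6.21 and -5.71), as did Cox7a2l (-3.94 and -3.82). Of 36 proteasome subunits, 22 fell and 1 rose in vivo (23 and 1 adjusted over the list alone), and 24 fell and 1 rose in vitro (26 and 1), and Psmc2 fell (-6.34 and -6.74). Relative to all genes the medians were -3.10 and -3.71 for ribosomal proteins, -2.39 and -2.30 for the respiratory chain and -2.89 and -2.60 for the proteasome. The camera adjusted p-values were 2.55e-13 and 1.23e-11, 8.26e-17 and 1.94e-12, and 6.34e-10 and 1.81e-09, and all 6 calls held with an estimated correlation (adjusted p from 0.0149 to 0.0228).

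Heat shock and stress genes were also lower at MII. Of 34 tested, 12 fell and 3 rose in vivo (14 and 3 adjusted over the list alone), and 12 fell and 1 rose in vitro (12 and 1), with camera adjusted p = 0.000783 and 0.00247. The chaperones Hspa8 (-3.80) and Dnaja1 (-3.15) fell in vivo. Among 25 maternal effect genes, needed by the early embryo, 12 fell and 3 rose in vivo (14 and 3 adjusted over the list alone), and 10 fell and 3 rose in vitro (12 and 3), with adjusted p = 0.000661 and 0.00316. Ooep, of the subcortical maternal complex, fell (-3.18 in vivo and -3.53 in vitro). The calls of maternal effect genes and subcortical maternal complex ended with the values as deposited (adjusted p = 0.06 and 0.0829) and with median scaling (0.0954 and 0.128). Of 34 oocyte-specific genes, 13 fell and 3 rose in vivo (13 and 4 adjusted over the list alone), and 13 fell and 2 rose in vitro (18 and 3). Oas1c (-4.93) and Zp2 (-4.43) fell in vivo. The adjusted p-values of 0.000661 and 0.000231 became adjusted p = 0.244 and 0.226 with an estimated correlation, and 0.463 and 0.381 with median scaling; with the values as deposited the call in vivo ended too (0.109).

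Mitochondrial genes outside the respiratory chain gave calls in vivo. Of 25 genes of mitochondrial biogenesis and dynamics, 9 fell and 3 rose, unchanged in number over the list alone, with the channel protein Vdac3 lower (-4.55) and Vdac1 higher (1.91) (camera adjusted p = 0.0122; adjusted p = 0.0364 with an estimated correlation). Of 23 pyruvate dehydrogenase and TCA cycle genes, 10 fell and 4 rose, in the same numbers over the list alone. Fumarase, Fh1, fell by 2.67 and Idh1 rose by 2.35 (adjusted p = 0.0217, and adjusted p = 0.0772 with an estimated correlation). In vitro the adjusted p was 0.0637 for both lists, with 8 falling and 4 rising in the first and 10 falling and 4 rising in the second.

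**Figure D2:**
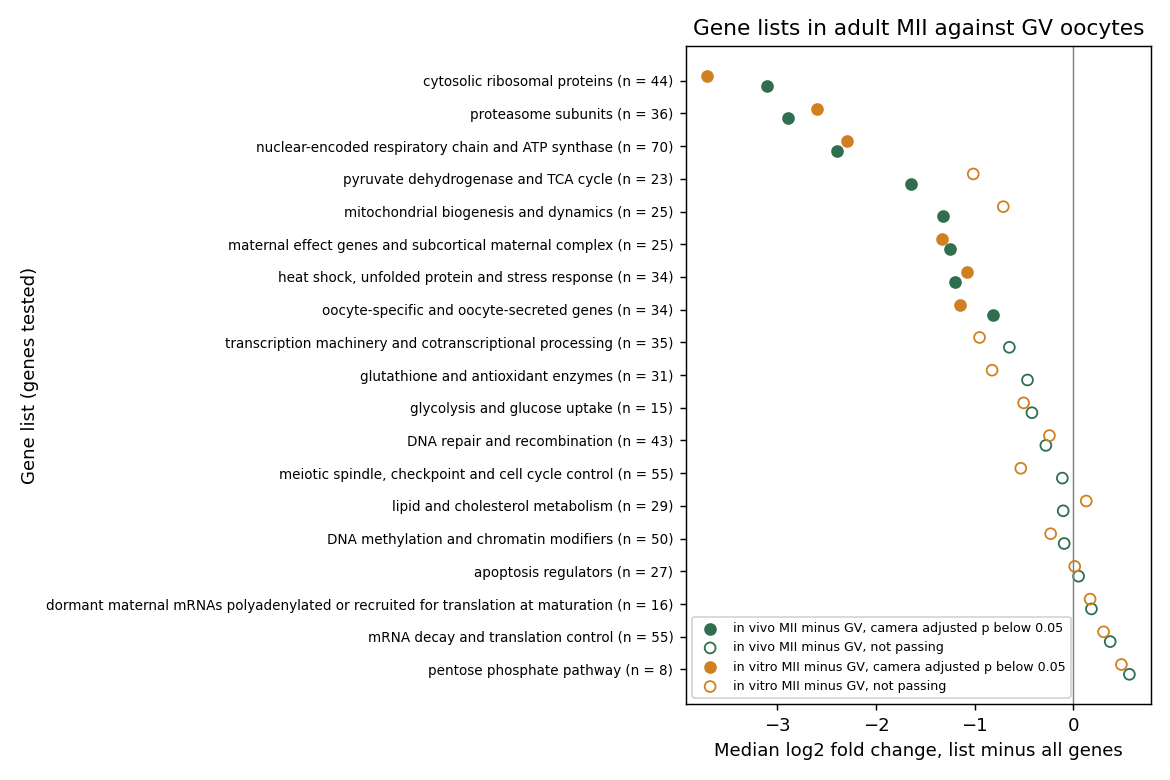
Points give the median log2 fold change of each of the 19 gene lists minus that of all tested genes (x axis) in adult MII against GV oocytes, for maturation in vivo (green, n = 3 against 2 arrays) and in vitro (orange, n = 2 against 2). Filled points passed camera at an adjusted p below 0.05, and ribosomal proteins lie lowest, at -3.10 and -3.71.

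Other lists held members that moved both ways and did not pass as lists. Among 55 genes of mRNA decay and translation control, 20 rose and 7 fell in vivo (22 and 8 adjusted over the list alone; camera adjusted p = 0.0934), and 19 rose and 8 fell in vitro (20 and 10; 0.285). The translational repressor Pum2 rose by 2.36 and the poly(A) polymerase Tent2 by 1.98 in vivo, while Paip2, which represses the poly(A) binding protein, fell by 4.27. Of 16 dormant maternal mRNAs, which gain poly(A) at maturation, 6 rose and 1 fell in vivo (8 and 1 over the list alone; 0.115), and 5 rose and 1 fell in vitro (6 and 2; 0.432). Orc6 rose by 1.70 and Hprt by 1.64 in vivo, and Cdc6 fell by 2.44. Of 50 DNA methylation and chromatin genes, 13 rose and 5 fell in vivo (14 and 6; 0.562), and 10 rose and 7 fell in vitro (10 and 7; 0.891). The DNA methyltransferase Dnmt3a rose by 2.44 and the deacetylase Sirt1 by 1.90 in vivo, and camera pointed up although the list median was -0.09 relative to all genes.

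Of 55 spindle and cell cycle genes, 15 rose and 15 fell in vivo (16 and 16 over the list alone; camera adjusted p = 0.447), and 11 rose and 17 fell in vitro (15 and 22; 0.0703). The kinases Ttk (-3.41) and Cdk1 (-4.83) fell in vivo, and the cohesin protector Sgo2a rose by 2.12. In transcription machinery 6 of 35 genes rose and 12 fell in vivo (8 and 14 over the list alone; 0.0934), and 6 rose and 11 fell in vitro (7 and 12; 0.0873). In DNA repair 9 of 43 rose and 10 fell in vivo (9 and 12; 0.454), and 10 rose and 12 fell in vitro (12 and 13; 0.605). In glutathione and antioxidant metabolism 5 of 31 rose and 6 fell in vivo (5 and 6; 0.254), with Sod1 lower (-3.25) and Gclc higher (2.17), and 4 rose and 7 fell in vitro (4 and 7; 0.201). Glycolysis had 2 rising and 3 falling genes of 15 in vivo (2 and 3; 0.454) and 2 and 4 in vitro (2 and 4; 0.432), with Hk2 higher (1.85) and Pkm lower (-3.65) in vivo. The pentose phosphate pathway had 2 rising and 1 falling of 8 in vivo (3 and 1; 0.52) and in vitro (2 and 1; 0.684), with Tkt lower (-5.04) in vivo. Lipid metabolism had 4 rising and 3 falling of 29 in vivo (4 and 2; 0.83) and in vitro (5 and 5; 0.891), and apoptosis regulators had 3 rising and 2 falling of 27 in vivo (3 and 2; 0.864) and 4 and 2 in vitro (4 and 1; 0.972).

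Stage and reference genes gave the following levels. Mos, the kinase that holds MII arrest through MAP kinase, was 11.49 ± 0.30 in GV oocytes (SD, n = 2) and 9.49 ± 3.20 in adult in vivo oocytes (SD, n = 3), and the difference (SE 1.62, adjusted p = 0.43) did not pass and was -0.26 without the dim arrays. In vitro the Mos difference was -4.29 (SE 1.77, adjusted p = 0.0887), with no overlap between arrays, and did not pass either. Plat, tissue plasminogen activator, was 13.15 ± 0.05 in GV oocytes (SD, n = 2) and 11.61 ± 1.16 in adult in vitro oocytes (SD, n = 2), a difference of -1.54 that did not pass (adjusted p = 0.0746) but passed at -0.63 without the dim arrays (adjusted p = 0.0285). Actb differed by 0.06 (SE 0.50) in vivo and -0.04 (SE 0.55) in vitro from GV, and the linker histone H1f8 by -0.25 (SE 0.90) and -0.80 (SE 0.99), none passing. With median scaling Gdf9 rose by 1.32 in vivo (adjusted p = 0.0154) and the Bmp15 probe set with the highest mean rose by 1.53 in vitro (0.0394), while another Bmp15 probe set was lower in vitro after quantile normalization (-2.60, adjusted p = 0.00911), and with the values as deposited Actb fell by 2.89 in vitro (0.0273). In the other comparisons none of these 7 genes passed by its probe set with the highest mean.

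Maturation in vivo was compared with maturation in vitro at d26. At this age 9 probe sets were higher in vivo and 0 lower, covering 7 genes. Both in vivo arrays had the highest 3' to 5' Gapdh ratios of the series (82.3 and 68.0), against 12.6, 16.5 and 26.8 in the in vitro arrays. The 5' signals were 0.76 and 3.99 in vivo and 22.8, 0.90 and 1.89 in vitro. Ratios over such low signals are imprecise. Ube2t, a ubiquitin-conjugating enzyme of DNA crosslink repair, was 11.24 ± 0.01 in vivo (SD, n = 2) and 8.63 ± 0.61 in vitro (SD, n = 3). The nuclear import receptor Kpna2 was 11.02 ± 0.43 in vivo (SD, n = 2) and 9.03 ± 0.26 in vitro (SD, n = 3). The others were Mtx2, a mitochondrial outer membrane protein (3.61, SE 0.56, adjusted p = 0.0348), Tm2d1 (2.80, SE 0.36, adjusted p = 0.0192), Slc35b3 (2.52, SE 0.34, adjusted p = 0.0201), Elobl (1.72, SE 0.25, adjusted p = 0.0225) and the dynein adaptor Bicd2 (1.59, SE 0.25, adjusted p = 0.0453). Mtx2 averaged 3.05 in vitro, under the filter level of 3.07. Without d26 in vitro replicate 3 all of the 7 but Mtx2 did not pass (adjusted p from 0.0829 for Tm2d1 to 0.151 for Bicd2), without d26 in vitro replicate 1 all but Tm2d1 and Slc35b3 did not (0.0522 to 0.0769), and without either GV array Mtx2, Bicd2, Kpna2 and Elobl did not (0.0651 to 0.115). Mtx2 and Bicd2 also did not pass without adult in vivo replicate 2 or 3 or d20 in vitro replicate 1 or 3 (0.0508 to 0.0906) or with no filter (0.0629 and 0.0794), nor did Bicd2 with the pseudocount (0.0516) or without either adult in vitro array or d20 in vitro replicate 2 (0.0564 to 0.0683). No list passed camera, the lowest adjusted p being 0.0562 for maternal effect genes, of which 0 of 25 passed singly and 3 rose over the list alone. The count was 0 with the values as deposited, in a fit to the compared arrays alone, with variances without a trend, and without either in vivo array. With the number in the sample titles as a block, split into those up to 12 and those above, whose meaning is not known, it was 1, and none of the 7 genes passed (adjusted p = 0.0917 for Tm2d1, Ube2t, Slc35b3, Kpna2 and Elobl and 0.177 for Mtx2 and Bicd2). It was 85 without the dim arrays, 48 with array weights, 28 with median scaling, 17 without adult in vivo replicate 1, 20 and 2 without d26 in vitro replicate 2 or 3, and 5 without either GV array.

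In adults the same comparison gave 1 probe set, without a gene name, and 0 genes by limma. Here 1801 probe sets had an unadjusted p below 0.05, where 1126 are expected by chance. The smallest p-values belonged to Wdtc1 (4.52, SE 0.68, adjusted p = 0.0975), Castor1 (3.40), Cby3 (3.49), Nat10 (2.18) and Saa3, the latter 4 with adjusted p = 0.291, all with higher means in vivo and no overlap between the 5 arrays. Wdtc1, Cby3 and Saa3 averaged under the filter level of 3.07 in vitro. The spindle and cell cycle list passed upward (median 0.21 relative to all genes, camera adjusted p = 0.0116, and adjusted p = 0.673 with an estimated correlation) although 0 of its 55 genes passed singly or over the list alone. For meiotic spindle, checkpoint and cell cycle control the adjusted p was 0.144, 0.0624 and 0.0957 without adult in vitro replicate 1 or 2 or adult in vivo replicate 3, and 0.138 with median scaling. Markers of stroma, blood and immune cells were higher in adult in vivo oocytes (camera adjusted p = 0.0416, and adjusted p = 0.207 with an estimated correlation), with 0 of 22 genes passing and 3 rising over the list alone. Lyz2, lysozyme, averaged 6.46 in vivo and 2.80 in vitro in adults, and Vim, vimentin, 5.68 and 3.66. The count was 412 without adult in vitro replicate 1, which leaves 1 dim array in that group, and 106 without the dim arrays. It was 8 without d26 in vitro replicate 2, 2 without adult in vivo replicate 1 or d26 in vitro replicate 3, and 0 without adult in vivo replicate 2 or 3.

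Averaged over d26 and adult oocytes, 44 probe sets were higher in vivo and 7 lower, covering 27 and 3 genes, with the d26 in vivo arrays of high Gapdh ratio (82.3 and 68.0) on the in vivo side. Tm2d1 was higher in vivo by 2.30 (SE 0.26, adjusted p = 0.00348), Ube2t by 2.05 (SE 0.27), Slc35b3 by 1.77 (SE 0.24), Kpna2 by 1.67 (SE 0.21) and Elobl by 1.39 (SE 0.18). The proliferation marker Mki67 (-1.37, SE 0.22, adjusted p = 0.0182), the tetraspanin Cd151 (-1.35, SE 0.24, adjusted p = 0.0328) and the membrane fission ATPase Vps4b (-1.40, SE 0.26, adjusted p = 0.0465) were lower in vivo. With the values as deposited these 3 differences were -0.33, -0.29 and -0.40 (adjusted p = 0.599 for Mki67, 0.696 for Cd151 and 0.523 for Vps4b), and with median scaling none of the 3 passed (0.0744, 0.0719 and 0.0918). Cd151 and Vps4b also did not pass without most single arrays, nor Mki67 without 5 of them. None of the 3 passed in a fit to the compared arrays alone (0.237 for Mki67, 0.254 for Cd151 and Vps4b) or with variances without a trend (0.0977, 0.121 and 0.156), and Vps4b did not with no filter (0.0508) or without the dim arrays (0.0965). Of the 5 genes higher in vivo, Tm2d1, Kpna2, Elobl and Slc35b3 did not pass with the values as deposited (adjusted p from 0.0677 to 0.136), and all but Tm2d1 did not with variances without a trend (0.0545 to 0.0669). Kpna2, Elobl and Slc35b3 did not pass in a fit to the compared arrays alone (0.0887, 0.103 and 0.103), and none of the 5 passed without d26 in vivo replicate 2 (0.0652 to 0.0807). Atp5a1 (-0.83, adjusted p = 0.0666) and Ifit1bl2 (-1.86, adjusted p = 0.0728) did not pass. The spindle list passed upward (median 0.28, camera adjusted p = 0.0149, and adjusted p = 0.73 with an estimated correlation), with the checkpoint protein Bub3 rising by 1.10 (SE 0.17, adjusted p = 0.0182) as the 1 of 55 genes that passed, and 5 rising over the list alone. For meiotic spindle, checkpoint and cell cycle control the adjusted p was 0.0701 and 0.0637 without adult in vitro replicate 1 or d26 in vitro replicate 1. The 4 lists of other cell types did not pass, with the lowest adjusted p at 0.143. The total of 51 calls moved by more than 1.5 times without any 1 array except d26 in vitro replicate 2, from 0 without d26 in vivo replicate 2 to 438 without adult in vitro replicate 1. It was 133 without the dim arrays, 3 in a fit to the compared arrays alone, 6 with the values as deposited, 11 with variances without a trend and 106 with array weights. With the title number as a block it was 6, all higher in vivo, and Slc35b3, Mki67, Cd151 and Vps4b did not pass (adjusted p = 0.0627, 0.0857, 0.0841 and 0.176).

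**Figure D3:**
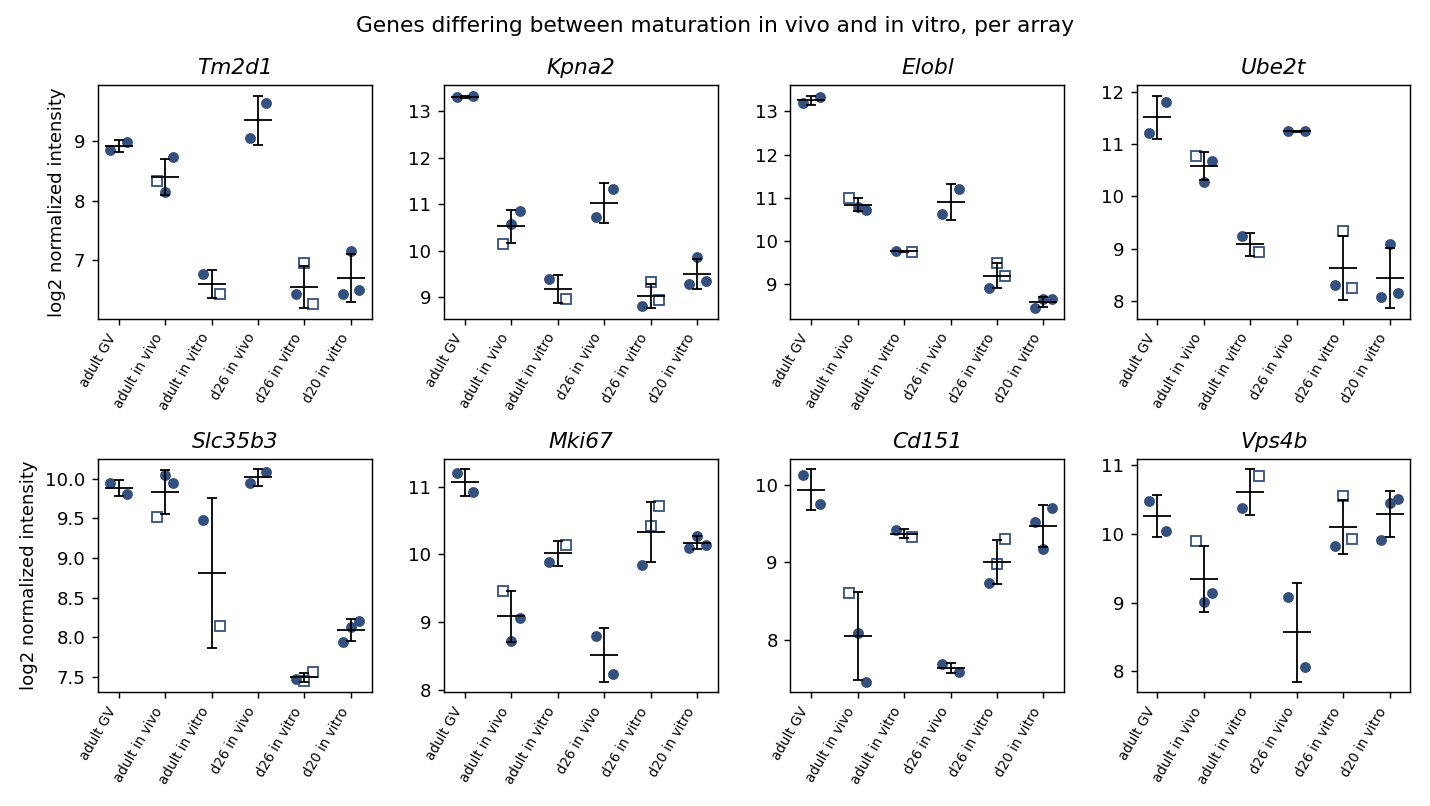
Each panel plots the log2 normalized intensity (y axis) of 1 gene on every array by group (x axis), with open squares for the 4 dim arrays and lines for the mean ± SD of the 2 or 3 arrays. Kpna2 averages 10.52 and 11.02 in the in vivo groups and 9.03 to 9.50 in the 3 in vitro groups, and Mki67 is lower in vivo after quantile normalization, a call that ended with the values as deposited, with median scaling and with the title number as a block.

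Whether the maturation difference itself changed with age was tested as an interaction. The smallest p-values belonged to Crx (-5.04, SE 0.97) and Myo7b (-4.65, SE 0.86), both with adjusted p = 0.548, Wdtc1 (-4.58), Ccdc102a (-3.75) and Pf4 (-5.14) on the negative side, and to Fam47e (6.03), Nup133 (4.86), Tbc1d14 (1.24), Mnat1 (3.25) and Fads2b (4.14) on the positive side. All but Tbc1d14 and Mnat1 averaged under the filter level of 3.07 in at least 1 MII group. None passed in limma, 0 probe sets were called, and 840 had an unadjusted p below 0.05 where 1126 are expected by chance. Without adult in vitro replicate 1 the count was 25.

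The question of age was addressed in oocytes matured in vitro. Against adults, d20 oocytes had higher signal for Wdtc1 (4.91, SE 0.68, adjusted p = 0.0189), for Prkcsh, a subunit of the glycoprotein-trimming glucosidase II (3.34, SE 0.49, adjusted p = 0.0328), and for the RNA acetyltransferase Nat10 (3.14, SE 0.43, adjusted p = 0.0189). The kinase Map3k21 was 5.31 ± 0.35 in d20 oocytes (SD, n = 3), 7.35 ± 0.36 in d26 oocytes (SD, n = 3) and 8.71 ± 0.36 in adult oocytes (SD, n = 2), and its d20 difference from adults of -3.41 (SE 0.36) passed (adjusted p = 0.00213). Wdtc1 and Prkcsh averaged 1.06 and 2.58 in adult in vitro oocytes, both under the filter level of 3.07, so the sizes of their differences are imprecise. Wdtc1 was 5.59 ± 0.48 in adult in vivo oocytes (SD, n = 3). The same adult in vitro arrays, of which replicate 2 was dim, also had lower means of Wdtc1 and Nat10 than adult in vivo and d26 in vitro oocytes. Those differences did not pass. An age difference of these genes cannot be told apart from low values in the adult in vitro arrays. Of 22519 probe sets 4 were higher and 1 lower, and 3971 had an unadjusted p below 0.05, where 1126 are expected by chance. Wdtc1, Nat10 and Prkcsh did not pass without either GV array, d20 in vitro replicate 1 or 3 or adult in vitro replicate 2 (adjusted p from 0.056 to 0.272), and Prkcsh did not without adult in vivo replicate 2 or 3, either d26 in vivo array or d20 in vitro replicate 2 either (0.0574 to 0.114). Map3k21 passed without each array in turn but not with the values as deposited (0.215) or in a fit to the compared arrays alone. Prkcsh did not pass with no filter (0.121) or with the title number, up to 12 or above, as a block (0.0919). No list passed, the lowest camera adjusted p being 0.0901 for oocyte-specific genes. The total of 5 was 0 with the values as deposited and in a fit to the compared arrays alone, 763 without adult in vitro replicate 1, and 325 without the dim arrays, where 1 adult in vitro array remains. It was 85 without adult in vivo replicate 1, 36 and 9 without d26 in vitro replicate 2 or 1, and 2 without either GV array or d20 in vitro replicate 1 or 3.

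Against adults, d26 oocytes had 1 higher probe set, without a gene name, and 0 genes by limma. There 1654 probe sets had an unadjusted p below 0.05, where 1126 are expected by chance. The smallest p-values belonged to Wdtc1 (4.34, SE 0.68, adjusted p = 0.155), the nucleoside diphosphate kinase Nme2 (-3.64, SE 0.66), Nat10 (2.36), the meiotic cohesin Smc1b (4.38) and Scarb2 (-3.47), the latter 4 with adjusted p = 0.292. Wdtc1 and Smc1b averaged under the filter level of 3.07 in adult oocytes, and Nme2 and Scarb2 did so in d26 oocytes, at 0.63 and 1.84, so these differences are imprecise, that of Nme2 between d20 and d26 included. Between d20 and d26, 0 probe sets passed in limma and 2581 had an unadjusted p below 0.05, where 1126 are expected by chance. Nme2 (4.21, SE 0.59, adjusted p = 0.06), Map3k21 (-2.05, SE 0.32, adjusted p = 0.0647), the ribosome biogenesis factor Bms1 (1.15), the Wnt agonist Rspo2 (1.14) and the transsulfuration enzyme Cth (-1.96) had the smallest p-values. A joint test of any age difference called 2 probe sets, Map3k21 among them. The joint test called 0 without d20 in vitro replicate 1, with the values as deposited and in a fit to the compared arrays alone, 368 without adult in vitro replicate 1, 214 without the dim arrays, 41 with array weights, and 22 with variances without a trend. It called 29, 17 and 10 without adult in vivo replicate 1 or d26 in vitro replicate 2 or 1. With the title number as a block it called 5, d20 against d26 called 2 and d26 against adults called 0. The count for d26 against adults was 307 without adult in vitro replicate 1 and 83 without the dim arrays, and it was 7, 5 and 0 without adult in vivo replicate 1, d26 in vitro replicate 2 and any other array but adult in vitro replicate 2; that for d20 against d26 was 28 without d26 in vitro replicate 1, 3 and 1 without adult in vitro replicate 2 or 1, and 33 without the dim arrays. Because d20 and d26 were set against the same adult arrays, their fold changes correlated at 0.633 across probe sets, below the 0.693 of 100 simulations with no effect, and their covariance was 0.721 against 0.584. These simulated values too depend on the array weights that set the noise, 0.51 for both adult in vitro arrays.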

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

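The measure of intensity over these controls was a test chosen only after its values were seen. Control probe sets that none of the comparisons used carried signal. The 3' probe set for dap, a bacterial gene used in standard poly(A) controls that are added before amplification, averaged 148 over the 15 arrays, 46.1 times the mean of 3.20 of the trp probe sets, which stand for a bacterial gene outside that mix; the labels do not mention such controls. Its deposited intensity was 55.5 and 97.3 in the GV arrays, 98.4 to 293 in the 9 brighter MII arrays and at most 79.5 in the 4 dim arrays. The measure was the median log2 intensity of the brightest 4504 probe sets minus the mean of dap, phe and thr. It was 5.50 ± 0.42 in GV arrays (SD, n = 2) and 3.85 ± 0.21 in the brighter MII arrays (SD, n = 9). The difference was -1.65 (exact permutation test, two-sided p = 0.0182, the smallest that 55 splits can give). The 4 dim arrays, all of MII oocytes, were left out of this test, and their values are not given. The difference is thus shown for the brighter MII arrays only, not for all MII arrays.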

How the results depend on the processing

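The totals of the comparisons with GV oocytes moved less than the small counts, but their direction depended on the scaling: with the values as deposited the 3542 higher and 2495 lower probe sets in vivo became 23 and 3481, and the 3607 and 2641 in vitro became 11 and 6224. Median scaling, the fit without the 4 dim arrays and the list tests with 1 array left out were chosen after seeing the data. Counts of called probe sets are given against the reported 5 for d20 minus adult, 1 for d26 minus adult, 0 for d20 minus d26, 2 for any age difference, 9 and 1 for in vivo minus in vitro at d26 and in adults, 51 for their mean, 0 for the interaction, and 6037 and 6248 for adult in vivo and in vitro minus GV. With the values as deposited they were 0 for d20 minus adult, 0 for d26 minus adult, 1 for d20 minus d26, 0 for any age, 0 and 0 for maturation at d26 and in adults, 6 for the mean and 3504 for in vivo minus GV. With no filter d26 minus adult had 0. With the upper 30% of probe sets d26 minus adult had 0, d20 minus d26 had 3, any age had 1 and adult maturation had 0. With the pseudocount d26 minus adult had 0 and any age had 1. In fits to the compared arrays alone d20 minus adult, d26 minus adult, any age and maturation at d26 and in adults had 0, and the mean had 3. With variances without a trend d20 minus adult had 18, d26 minus adult 6, any age 22, maturation 0 at d26 and 5 in adults, and the mean 11. With array weights d20 minus adult had 12, d26 minus adult 0, d20 minus d26 19, any age 41, maturation 48 at d26 and 0 in adults, the mean 106 and in vivo minus GV 10291. With the title number as a block d26 minus adult had 0, d20 minus d26 had 2, any age 5, maturation at d26 1 and the mean 6. With median scaling maturation at d26 had 28 and any age 1. Without the 4 dim arrays d20 minus adult had 325, d26 minus adult 83, d20 minus d26 33, any age 214, maturation 85 at d26 and 106 in adults, and the mean 133. Leaving out 1 array at a time gave 2 to 763 for d20 minus adult, 0 to 307 for d26 minus adult, 0 to 28 for d20 minus d26, 0 to 368 for any age, 0 to 20 and 0 to 412 for maturation at d26 and in adults, 0 to 438 for the mean, 0 to 25 for the interaction, 3308 to 6757 for in vivo minus GV and 3795 to 6986 for in vitro minus GV. Where 1 array remained in a group, it was assumed to vary like the other groups. The cause of these changes was not tested, beyond the fewer arrays in fits that leave arrays out.

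Of 600 values of named genes in the GV comparisons with 1 array left out, 584 kept their call, 16 lost it and 0 reversed, and under the other settings 367 of 380 kept it and 13 lost it. In the other comparisons 577 of 690 and 360 of 448 kept their side of the threshold, and 1 reversed, Atp5a1 at 0.18 with the values as deposited against -0.83. Of 240 list medians with 1 array left out, 235 kept their call, and of 80 under other settings 67 did. The low end of the intensities limits the large rises, since MII genes that start near background in GV oocytes have no detection calls here.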

Other observations

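Gene families outside the fixed lists, grouped by the start of their symbols and chosen after seeing the data, moved in the comparisons with GV oocytes. Of 42 large subunit proteins of the mitochondrial ribosome (Mrpl), 16 fell and 3 rose after maturation in vivo (camera adjusted p = 9.84e-05 over 45 families, and adjusted p = 0.0756 with an estimated correlation), and of 28 small subunit proteins (Mrps), 15 fell and 0 rose (0.000201, and adjusted p = 0.104 with an estimated correlation). Of 10 Eif3 subunits of the translation initiation factor, 6 fell and 1 rose (0.013, and adjusted p = 0.104 with an estimated correlation).

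Among genes with means of at least 8 on the log2 scale in both groups, also chosen after their values were seen, 1098 passed in adult in vivo MII against GV oocytes. The largest rises were ND5 (2.80), a mitochondrially encoded subunit of complex I, the phosphodiesterase Pde3b (2.44) and the deubiquitinase Usp15 (2.42). The largest falls were Elp2 (-4.67), an Elongator subunit, Tmsb10 (-4.55), thymosin beta, Zp2 (-4.43) and Oser1 (-4.32). In vitro, Smad1 rose by 3.40 and Bud31, a splicing factor, fell by 4.69. All these sizes are after quantile normalization, and those under other scalings are not given for this selection. With the values as deposited only 23 probe sets were higher than in GV oocytes in vivo and 11 in vitro.

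In the weighing that follows, the splits of the samples and the leukocyte tests were fixed before their results were seen, though the leukocyte genes were written down after the rises of Ctss, Saa3 and the immune markers were known, and all other tests were chosen only after the result was seen. For the genes higher in vivo, the tests of dim arrays and of other cells replaced earlier versions that had been run and had been read as arguing against those sources: the median d20 in vitro minus in vivo difference on the brighter arrays (-1.31), set aside because the genes were chosen on those in vivo arrays, and the median GV level of the genes (10.4), set aside because expression in GV oocytes does not exclude added RNA.

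More genes were higher in vivo than in vitro. Without the dim arrays 124 probe sets were higher, with 20 of the 27 called genes among them. This does not decide whether the dim arrays are the source. Only a single array then remains in each of the adult and d26 in vitro groups. The 27 genes were also chosen with the remaining arrays among those compared. RNA of other cells stays open: the marker genes of other cell types gained a median of 2.79 intensity units, but most lie near background and the called genes were selected for their gain, so that value decides nothing, and the RNA quality of the d26 in vivo arrays, with 3' to 5' Gapdh ratios of 82.3 and 68.0, is open and untested too. Chance is not excluded: 7 of the 100 splits within age gave as many as the real 51 probe sets, the highest other 3627, a split that put all 4 dim arrays on one side, which points to a structure of the samples. A candidate explanation, with maturation conditions left open as an untested difference, is a larger fall between GV and MII in vitro: in d20 in vitro oocytes, which were on neither side of the comparison but entered its normalization, filter and variances, the 27 genes lay at a median of -2.36 from GV, below all of 1000 level-matched random sets (median 0.66), and 25 of 27 were lower, though only 11 of 27 passed as falling from GV in adult in vivo oocytes, so for most a fall in vivo was not shown. The random sets were matched on the mean over all arrays rather than on the GV level. The genes were chosen for low values in oocytes matured in vitro, as the d20 oocytes were. Their place below the random sets is therefore weak support.

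For d20 against d26, where 0 probe sets were called, all 10 of 10 splits gave as many, as a real count of 0 fixes in advance, the highest other was 0, and so few splits cannot give a share under 0.05 in any case. By limma 2581 probe sets had an unadjusted p below 0.05, where 1126 are expected by chance. That excess cannot be told apart from array brightness, since d26 in vitro replicates 2 and 3 were dim and no d20 array was.

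Ctss and Slfn4, known from leukocytes, were among the 10 largest rises in adult in vivo oocytes, with 1 oviduct gene, Ovgp1, whose list did not pass (adjusted p = 0.666 against GV) and held falls such as Ehf (11.11 to 5.97). A candidate source is RNA of leukocytes carried with ovulated oocytes despite the hyaluronidase step: a second list of 24 leukocyte genes, 0 of them on the fixed marker list and 1 at 8 or more in GV oocytes, was higher there than in the mean of the other MII groups by a median of 0.66, against a 95th percentile of 0.33 among 10000 level-matched lists, with 20 of 24 genes higher, among them S100a8 by 3.61, S100a9 by 3.09 and Tyrobp by 2.66. A single array is not the source, since the list exceeded the 95th percentile in all 3 arrays, with medians of 1.15, 0.85 and 0.69. Under the values as deposited and median scaling the list lay at the 99.9th percentile. These are a single test, because a shift of a whole array moves every list alike. Without the dim arrays the median was 0.56, against a 95th percentile of 0.40 among level-matched lists. Only a single array then remained in each of the adult and d26 in vitro groups. Most of these genes are near background (median 4.36 in adult in vivo oocytes), Cd48 (-1.43) and Itgam (-0.33) were lower, and expression by the oocytes themselves stays open and untested. The d26 in vivo oocytes were among the other MII groups, and the second list was not tested in them alone. The fixed stroma, blood and immune markers had medians of 3.38 and 3.05 in the d26 in vivo arrays and 2.28 to 3.72 in the d26 in vitro arrays. The higher signal is thus shown for the adult in vivo group, not for oocytes matured in vivo in general.

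Ribosomal, respiratory chain and proteasome genes were lower at MII than in GV oocytes. The dim arrays and the quantile normalization do not account for the fall relative to all genes. The highest of the 6 list medians on that scale was -2.27 without the dim arrays, where only adult in vitro replicate 1 remains in its group. With the values as deposited or median scaling the highest was -2.33. These scalings are a single test, because a shift of a whole array cancels in a median relative to all genes. For the same reason the medians do not test a change in all mRNA. A candidate explanation that stays open is a shorter poly(A) tail rather than loss of mRNA, since RNA was isolated by its poly(A); mRNAs that gain poly(A) at maturation had a median of 0.18 and did not pass, and no value here separates tail length from amount. Degradation of these mRNAs during maturation is the other open explanation, and the 2 cannot be told apart.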
